A study of Mus musculus with 2 samples.

How the data were processed

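Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on cells from Glis2-HA mice, in which the Krüppel-like zinc finger transcription factor GLIS2 carries an HA tag. An antibody against the HA tag pulled down chromatin for 1 library (HA IP), and a second library was made from chromatin without antibody (input). The sample labels describe the material as primary renal epithelial cells, whereas the series text speaks of kidneys. There was 1 library per group, so no error between replicates could be computed and no test across samples was made. An IP from untagged cells was not analysed here.

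The values are counts of DNA fragments per peak region, as deposited by the authors, with no scaling to library size. Both libraries were counted over the same 30796 regions of 300 bp, none of which overlapped another. The genome build was mm10, per the submitters' processing notes, which also name cutadapt 1.12, Bowtie 1.2, Picard 1.110, HOMER 4.10.3 and bedtools (given as 2.29.2 and as 2.92.2) without their roles or settings. How peaks were called, whether duplicate fragments were removed and how fragments were counted are not given in the sources used here. The counts cover the peak regions alone, so the depth of either library over the whole genome is unknown. A ratio of IP to input counts therefore ranks peaks within this pair of libraries and is not a fold enrichment corrected for depth.

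For each peak, the ratio of IP to input counts was given an exact (Clopper-Pearson) 95% interval from the IP share of both counts, which covers counting error only. Summaries over peaks used (IP + 1)/(input + 1). A peak was called above the typical ratio when its interval lay wholly above 2 times the median over peaks, and below it when the interval lay wholly below 1/2 of the median. On simulated counts for 30796 peaks with 200 changed peaks, this rule called 55% of 100 peaks set at 4 times the common ratio, 100% of 100 peaks set at 8 times, and 0.0065% of the unchanged peaks; the intervals held the true ratio in 97.0% of peaks.

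Gene positions came from a table of 49997 RefSeq genes of GRCm38.p6, the assembly behind mm10, 21900 of them protein-coding. The table gives each gene's outer coordinates but no strand and no exons. Transcription start sites could therefore not be told from 3' ends, and the planned promoter class was replaced by gene ends. Start sites of shorter transcripts inside a gene were not known either. A peak inside a gene may thus lie at a promoter. A peak was placed at a gene end when its centre lay within 1000 bp of either outer coordinate of a protein-coding gene, and "lower end" and "higher end" below refer to chromosome coordinates. Random positions, 10 per peak on the same chromosome, gave the shares of each location without regard to binding. No genome sequence was used here, so the 23 sequence motifs listed beforehand, the GLIS site among them, were not searched, and promoter CpG content could not be used for matching.

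Gene lists for kidney disease, signalling, nephron segments and other cell types were fixed before the data were examined, as were the processing alternatives and the rule for naming peaks and genes. All 524 entries of the 22 lists (506 different genes) matched the gene table by symbol or synonym. For each list, the number of genes with a peak at either end was compared with 10000 random lists of the same size, matched on 5 classes of gene length and 3 classes of gene density (genes within 100000 bp), over 21631 protein-coding genes on the numbered chromosomes and X. The percentile counts random lists with fewer such genes plus 1/2 of the ties. It describes these libraries and is not a p-value, since genes are not replicates. Of 200 simulated lists of 25 genes drawn at random, 5.5% fell outside the central 95% of their random lists by percentile. The named items are the 12 peaks with the highest lower bound of the ratio, the 10 with the highest IP count, the 5 with the highest input count, up to 4 genes per list with the highest lower bound at an end, and Glis2, Ptch1, Gli1 and Cdkn1a whatever their values. Some items that this rule selects are not reported here. A peak took the name of the protein-coding gene with the nearest end. Genes outside this rule, named to illustrate a list or its members without an end peak, were chosen after their values were seen. Alternatives covered the scaling, the pseudocount, the interval, the distance to a gene end, the height of the peaks and the matching of random lists. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.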

Results

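To locate genomic regions occupied by GLIS2, HA-tagged GLIS2 was immunoprecipitated from renal epithelial cells of Glis2-HA mice and compared with input chromatin, with 1 library each. GLIS2 is a zinc finger transcription factor whose loss causes nephronophthisis, a cystic and fibrotic kidney disease. Over 30796 peak regions of 300 bp, the HA IP library held 5229946 fragments and the input library 172055. The median peak had 128 IP fragments (interquartile range 71 to 235, range 24 to 931) and 5 input fragments (interquartile range 3 to 7, range 0 to 23). The input count was 0 in 295 peaks. Input counts this low set the precision: at the median counts, the ratio of IP to input was 25.6 with an exact 95% interval of 10.7 to 80.2. All 30796 peaks had more IP than input fragments by this interval, in counts not corrected for depth. Since the regions are peaks, this was probably set by their choice and is no test of binding.

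The first question was where in the genome the peaks lay. Peaks of the HA IP were concentrated at the ends of protein-coding genes. Of 30796 peaks, 9349 (30.4%, exact 95% interval 29.8 to 30.9%) were centred within 1000 bp of a gene end, against 3.16% of random positions, a 9.61-fold excess. The excess was smaller, 5.31-fold and 5.58-fold, against the same peaks moved by 10000 and 100000 bp (5.71% and 5.44%). Within 100 bp of a gene end lay 5162 peaks (16.8%), against 0.331% of random positions. Another 12103 peaks (39.3%) lay inside protein-coding genes away from their ends, close to the 38.9% of random positions. Outside such genes lay 9344 (30.3%), against 58.0% of random positions. The shares add up to the whole, so the excess at gene ends lowers the others. The like shares inside genes therefore do not exclude a preference for them over regions outside genes. The 100 bp just outside gene ends held 2722 peak centres and the 100 bp just inside held 2431.

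**Figure D1:**
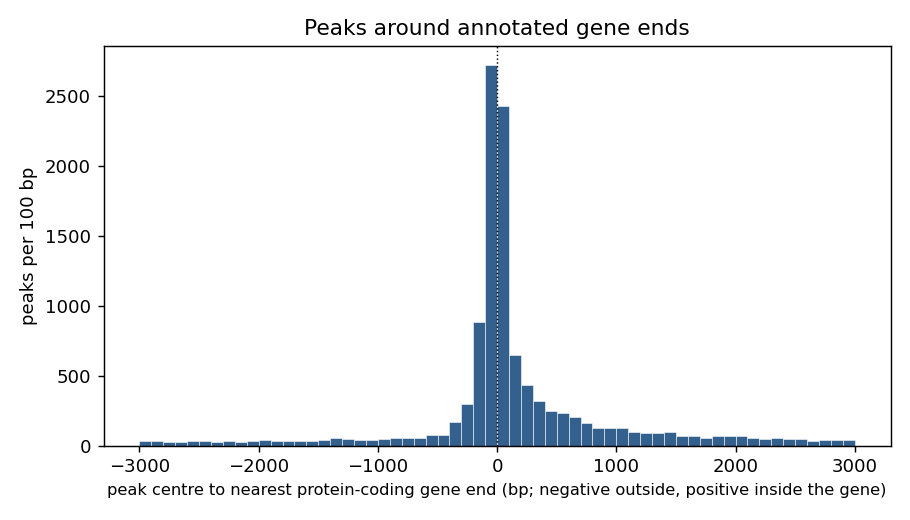
Number of peaks per 100 bp bin (vertical axis) by distance in bp of the peak centre from the nearest end of a protein-coding gene (horizontal axis, negative outside and positive inside the gene). The bins on either side of the gene end hold 2722 and 2431 peaks.

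Among 21631 protein-coding genes on the numbered chromosomes and X, 10026 (46.4%) had a peak at an end, and 12738 (58.9%) had one at an end or inside. The peaks marked one end of a gene and seldom both. Of 13889 genes longer than 10000 bp, 7205 had a peak at exactly 1 end and 351 (2.53%) at both, whereas independent marking of the ends would give 8.10%. Of the gene-end peaks, 1455 (15.6%) were within reach of the ends of more than 1 gene, so that the gene they belong to is uncertain.

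Peaks at gene ends were also the stronger ones. They had a median of 233 IP fragments (interquartile range 147 to 336), compared with 104 (62 to 181) inside genes and 91 (56 to 155) outside genes. Input fragments were higher at gene ends too, with a mean of 6.89 per peak against 5.12 inside and 4.89 outside genes. The median of (IP + 1)/(input + 1) was 29.8 at gene ends, 18.6 inside genes and 17.0 outside, so that gene ends exceeded all other peaks 1.67-fold (bootstrap 95% interval over peaks 1.64 to 1.71). Of the 25% of peaks with the most IP fragments (235 to 931), 60.1% lay at gene ends, and of the 25% with the fewest (24 to 71) 7.61% did. Mean input was 7.33 fragments per peak in the former and 3.85 in the latter. Peaks are not replicates, and these values describe 1 pair of libraries.

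**Figure D2:**
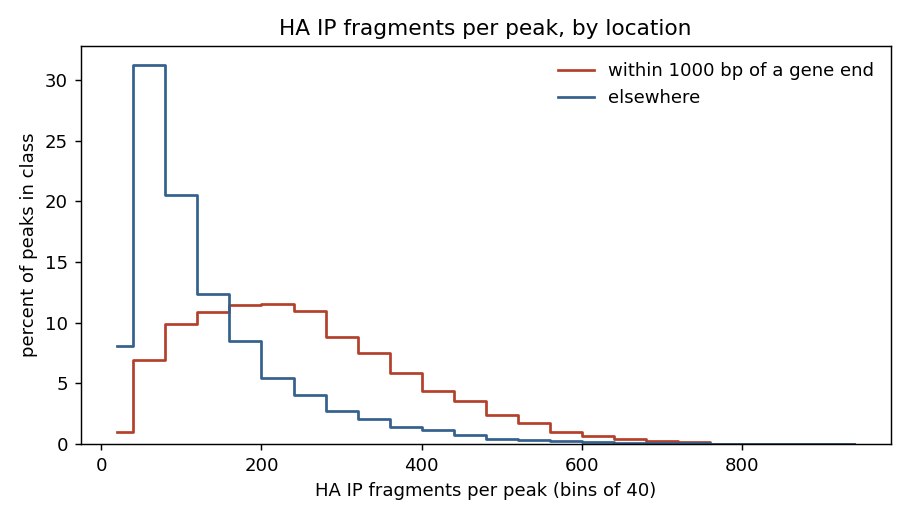
Percent of peaks in each class (vertical axis) by HA IP fragments per peak in bins of 40 (horizontal axis), for peaks within 1000 bp of a gene end (red) and elsewhere (blue). The medians are 233 fragments at gene ends, and 104 inside and 91 outside genes elsewhere.

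A second comparison ranked the peaks by their ratio. The median of (IP + 1)/(input + 1) was 21.2 (interquartile range 13.2 to 35.4). With low input counts, the intervals separated few peaks from it. Wholly above 2 times the median lay 624 (2.03%), and wholly below 1/2 of it lay 40 (0.13%). The intervals are those of the plain ratio, whereas the added 1 lowers the median, which was 23.3 with 0.5 added. Both limits are therefore low for these intervals, which favours calls above and disfavours calls below. Other pseudocounts were not tried for these calls. Of the 624, 323 (51.8%) were at gene ends, and of the 40, 2 were.

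The highest ratio by lower bound belonged to a peak inside Alpl, the gene of tissue-nonspecific alkaline phosphatase (chromosome 4, 137747114 to 137747413, mm10), 5532 bp from a gene end. It had 564 IP fragments and no input fragment, with a lower bound of 152 for the ratio. Of the 12 peaks ranked highest, 5 were at gene ends. All 12 had 0 to 3 input fragments, and none was among the 12 highest by IP count or by IP minus input count, so these names depend on the ranking. A peak 387 bp outside Nuak2, a kinase related to AMPK, had 611 IP fragments and 1 input fragment (ratio 611, interval 109 to 24172). One at Kmt2b, a histone H3 lysine 4 methyltransferase, had 537 and 1, and one at Foxj3, a forkhead factor, 764 and 3. Abcd3, a peroxisomal fatty acid transporter gene, had 629 IP and 2 input fragments at an end. Niban1 (731 and 2), Kcnk5 (373 and 0) and Celsr2 (325 and 0) held their peaks inside the gene, away from its ends. The remaining 3 peaks were outside protein-coding genes, with Rgs14 (6179 bp away), Hs6st1 (54312 bp) and Ctdp1 (55585 bp) as the genes with the nearest ends.

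By IP count alone, the strongest peak had 931 IP and 13 input fragments (chromosome 17, 69417403 to 69417702) and lay outside genes, 20359 bp from an end of Akain1. The second, with 899 IP fragments, was inside Tns1, which encodes the focal adhesion protein tensin 1; the nearest gene end was that of Rufy4, 65829 bp away. A peak inside Rara, the retinoic acid receptor alpha gene, had 813 IP fragments and was named by rule after Gm46294, 9393 bp away. Gene-end peaks among the 10 highest were those of Ubfd1 (861 IP fragments), Zhx1 (856), Faf1 (852) and Ralb (819). Peaks inside Unk (866), Cnnm2 (854) and Hs6st1 (813), over 1000 bp from any end, complete the list. The 5 highest input counts, 19 to 23, were at ends of Nsmce2, Serinc1, Ccdc151 and Tmem17 and outside genes 92863 bp from an end of Dpt, where IP counts of 210 to 379 gave ratios with lower bounds of 6.63 to 12.6.

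The labels name GLIS2 as the tagged protein, and its own gene carried peaks. Glis2 (gene ID 83396, chromosome 16, 4594320 to 4625141) had a peak of 337 IP and 9 input fragments at its lower end, centred 127 bp outside the gene (ratio 37.4, interval 19.5 to 82.6). A second peak inside the gene (4614706 to 4615005) had 186 and 9. At the higher end a peak had 179 and 12. Pam16 ends there as well, so the gene to which this peak belongs is uncertain. Ptch1, the Hedgehog receptor gene (chromosome 13, 63508328 to 63573460), had 184 IP and 12 input fragments at its higher end, a ratio of 15.3 (8.57 to 30.2), and 141 and 5 inside. Gli1, a transcriptional target of Hedgehog signalling, had no peak at its ends or inside, and the nearest was 18156 bp away. Cdkn1a, which encodes the cell cycle inhibitor p21, had 3 peaks inside with 140 to 154 IP fragments and none at an outer end. The 3 lay close together, between positions 29093496 and 29095694 of chromosome 17. Whether a start site inside the gene lies there was not tested.

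**Figure D3:**
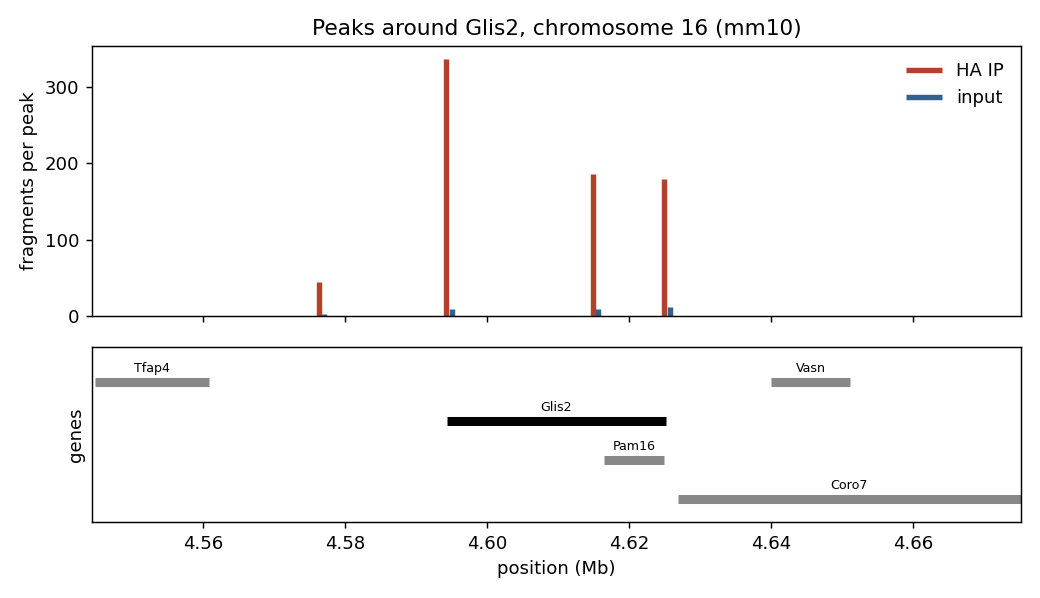
Fragments per peak (upper panel, vertical axis) in the HA IP (red) and input (blue) libraries at the 4 peaks around Glis2 on chromosome 16, with protein-coding genes drawn to scale below and position in Mb on the horizontal axis; input bars are set slightly to the right. The peak at the lower end of Glis2 is the tallest, with 337 IP and 9 input fragments.

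The study asked which genes GLIS2 targets, and gene lists fixed beforehand were used to describe the genes with end peaks. Genes of cilia and of cystic kidney disease carried end peaks more often than matched random lists. In the list for nephronophthisis and cystic kidney, 23 of 29 genes did (79.3%, percentile 99.51, central 95% of random lists 11 to 21 genes). Among them were Cep290 (640 IP and 10 input fragments), which encodes a protein of the ciliary transition zone, Dnajb11 (557 and 8), Dzip1l (421 and 5) and Sdccag8 (329 and 3). Pkd1, Pkd2, Anks6 and Zfp423 were among those with peaks only inside the gene, and Nek8 had none. The nephronophthisis list contains Glis2 itself. Within 500 bp of an end, 19 of its genes had a peak, at percentile 95.2.

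Ciliary transport and assembly genes showed 31 of 39 with an end peak (79.5%, percentile 99.95). Arl3, a small GTPase of ciliary cargo release, had 432 IP and 1 input fragment, with a ratio of 432 (77.1 to 17102). Bbs5 (345 and 4), of the BBSome, and Ift122 (292 and 3) and Ift140 (554 and 9), both of the retrograde intraflagellar transport complex, followed. The ciliary list's exceptions included Foxj1, Mks1 and Tctn2, which had no peak at an end or inside. The Hedgehog list had 12 of 17 genes with an end peak, at percentile 95.5, within the range of random lists. Its highest lower bounds of the ratio were at Gas1 (583 and 6), Cdon (241 and 3), Dhh (263 and 5) and Smo (185 and 3).

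Growth control lists also lay high. Of 22 Hippo-YAP genes 16 had an end peak (percentile 98.5), among them Yap1 (481 IP and 8 input fragments), Lats1 (342 and 2), Stk3 (360 and 3) and Ccn1 (246 and 2). Of 25 genes of p53, cell cycle arrest and senescence 17 did (percentile 99.3), with Cdkn1b (501 and 7), Sesn1 (399 and 6), Ccne1 (201 and 2) and E2f3 (265 and 5) in front. The Hippo-YAP call was lost within 500 bp of an end (percentile 91.2), and the p53 call among the 25% of peaks with the most IP fragments (percentile 72.1). Ribosomal protein genes, included as a reference of genes active in nearly every cell, reached 21 of 24 (87.5%), above the maximum of 16 in 10000 random lists. Rpl7 (580 and 7) and Rps19 (519 and 9) were among those with the highest bounds. Random lists were drawn from all protein-coding genes, which include large families with hardly any end peak. Examples are the olfactory receptor genes (0 of 1110) and vomeronasal receptor genes (1 of 355). Such genes lower the counts of random lists.

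Markers of cell types outside the epithelium seldom had end peaks. In the fibroblast, pericyte and mesangial list 1 of 18 genes did (percentile 0.005), namely Cspg4 (334 and 5). Neither Pdgfra, Pdgfrb nor Col1a1 had a peak at an end or inside; 7 of the 18 genes are also on other lists. The leukocyte list had 2 of 20 (percentile 0.015), Fcer1g (70 and 4) and Cd3e (77 and 6), both under the median IP count of 246 for the best end peak of a gene. Its call ended within 5000 bp of an end (8 genes, percentile 2.66). Endothelial genes had 5 of 18 (percentile 2.66, within the range), Tie1 (150 and 2), Ehd3 (134 and 10), Kdr (82 and 6) and Cdh5 (73 and 6) being the highest by lower bound. The endothelial list moved below the range among the 25% of peaks with the most IP fragments (0 genes, percentile 0.165) and with 3 and 8 length classes (2.41 and 2.44). It stayed within the range at 500 bp (percentile 6.79), at 5000 bp (10 genes, 26.7) and against unmatched random lists (5.98). Genes of neurons, liver and muscle had 4 of 26 (percentile 0.04): Apoa1 (131 and 6), Cyp2e1 (104 and 6), Fga (100 and 6) and Snap25 (50 and 4).

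Nephron segment lists lay within the range of random lists. Proximal tubule genes had 15 of 24 with an end peak (percentile 90.9), including the water channel gene Aqp1 (587 IP and 4 input fragments), Slc5a12 (260 and 1), the endocytic receptor gene Lrp2 (395 and 3) and Pck1 of gluconeogenesis (461 and 4). Loop of Henle and distal tubule genes had 11 of 22 (percentile 38.9), led by Wnk4 (386 and 5), Trpm7 (620 and 12), Stk39 (381 and 6) and Kcnj16 (293 and 4). Collecting duct genes had 9 of 23 (percentile 24.2), with Elf3 (434 and 6), the sodium channel gene Scnn1a (418 and 6), Krt7 (279 and 11) and Slc26a4 (63 and 1). Podocyte genes had 10 of 16 (percentile 90.9), with Actn4 (339 and 8), Podxl (156 and 2) and Cd2ap (408 and 12). Within 5000 bp of an end, proximal tubule and podocyte genes moved above the range, with 23 and 14 genes (percentiles 99.995 and 99.6). Kidney epithelial transcription factors had 12 of 33 at the ends (percentile 15.4), led by Irx3 (283 and 1), Esrra (337 and 5), Ppara (635 and 15) and Esrrg (197 and 3). For this list, 24 genes had a peak within 5000 bp (percentile 98.4); Pax8 and Hnf4a each had 5 peaks inside and none at an end.

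Lists for fibrosis, inflammation, signalling and metabolism also lay within the range at 1000 bp, although single members had strong peaks. Extracellular matrix and TGF-beta genes had 13 of 30 (percentile 20.4), led by the signal transducers Smad3 (738 and 4) and Smad4 (511 and 3) and the inhibitory Smad7 (639 and 5). Inflammation and tubular injury genes had 11 of 29 (percentile 32.4), led by Tnfaip3 (336 and 3), Icam1 (368 and 5), Nfkbia (259 and 3) and Stat3 (358 and 8), of which Tnfaip3 and Nfkbia encode NF-kappaB regulators. Wnt and beta-catenin genes had 17 of 30 (percentile 77.1), including Ctnnb1 (347 and 3), Apc (474 and 4), Fzd1 (340 and 2) and Fzd4 (471 and 5). Epithelial-mesenchymal transition genes had 8 of 22 (percentile 24.7), with Grhl2 (380 and 10), Ocln (268 and 9), Zeb1 (139 and 4) and Zeb2 (116 and 3). Cholesterol and fatty acid synthesis genes had 18 of 26 (percentile 96.0), with Mvk (378 and 3), Lss (326 and 5), Hmgcs1 (418 and 8) and Sqle (287 and 5). This list moved above the range within 5000 bp of an end (24 genes, percentile 99.9), against unmatched random lists (98.8) and with 3 length classes (97.6). AP-1 and immediate early genes had 8 of 20 (percentile 72.02), with Atf3 (340 and 3), Egr1 (264 and 5), Fosl1 (198 and 3) and Ier3 (287 and 6). Neither Jun, Junb, Jund nor Fos had a peak at an end or inside. The family of Glis, Gli and Zic genes had 2 of 11 (percentile 3.41), Glis2 and Gli3 (58 and 1), and moved below the range within 500 bp of an end (1 gene, percentile 1.42).

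**Figure D4:**
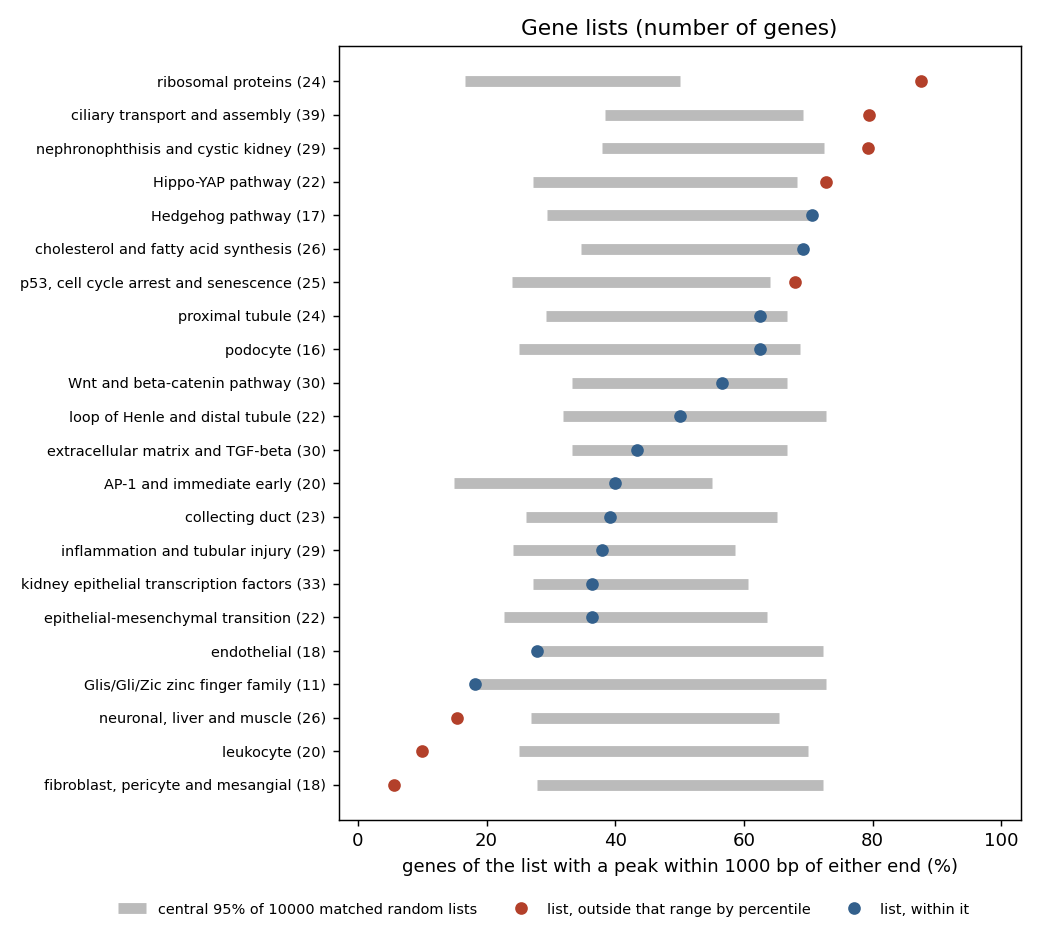
Percent of each list's genes with a peak within 1000 bp of either end (horizontal axis), by list with its number of genes (vertical axis); points are the lists and grey bars the central 95% of 10000 matched random lists. Ribosomal, ciliary and nephronophthisis genes lie to the right of the bars, and fibroblast (1 of 18) and leukocyte genes (2 of 20) to the left.

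Of the 22 lists, 5 lay above the central 95% of random lists by percentile and 3 below it, where 1.1 would lie outside by chance. The 5 include the ribosomal reference, and the 3 include the reference genes of other tissues. Of 165 gene families grouped by symbol, 53 lay above and 54 below, so such a count is not particular to these lists. Percentiles compare genes within this pair of libraries, and the lists could not be matched on expression or CpG content.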

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

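The tests with peaks moved along the chromosome, with the lowest 25% of peaks and with other length classes were chosen after the data were seen. No paired analysis was possible because each group had 1 library, and for the same reason none could be left out. Dividing each library by its total over the peaks turned the median ratio of 21.2 into 0.70, relative to the average peak, and pseudocounts of 0.5 and 5 gave 23.3 and 12.9. After that division, 2194 peaks had an interval above 1. The 624 peaks above 2 times the median became 218 with a 99% interval, 1907 with a factor of 1.5, 69 with a factor of 3 and 233 with at least 5 input fragments; the 40 peaks below 1/2 of it became 6, 188 and 1 under the first 3 of these. The share of peaks at gene ends, 30.4%, was 16.8% within 100 bp, 26.7% within 500 bp, 40.9% within 5000 bp, 35.6% for ends of all genes, 60.1% and 47.4% in the top 25% of peaks by IP count and by ratio, and 7.61% in the lowest 25% by IP count. Peaks moved by 10000 and 100000 bp gave 5.71% and 5.44%. The 1.67-fold higher ratio at gene ends was 1.53 within 100 bp and 1.75 with at least 5 input fragments. Of 506 list genes, 260 had an end peak, and 138 had one among the 25% of peaks with the most IP fragments. None of the 12 peaks with the highest ratio bound was among the 12 highest by IP count (0 shared) or by IP minus input count (0 shared), since peaks with 0 to 3 input fragments lead the former. List calls changed for up to 5 of 22 lists in a setting: within 500 bp 2 were lost and 1 gained, within 5000 bp 1 and 4, among those 25% of peaks 1 and 1, with unmatched lists 0 and 1, and with 3 and 8 length classes 0 and 2 and 0 and 1. No called list turned to the other side in any setting. Motif results, CpG-matched lists and alternatives by transcript were not run, for want of sequence, strand and exons. Input depth limits the ratio of single peaks, since the median peak had 5 input fragments.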

Other observations

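Peaks also separated gene families, grouped after the data were seen by the letters that open their symbols. Of 165 families with at least 15 genes, 53 lay above the central 95% of matched random lists by percentile and 54 below it, where 8.25 would fall outside by chance. Genes of RNA polymerase subunits (Polr) had an end peak in 28 of 28 cases, mitochondrial ribosomal proteins (Mrps) in 27 of 29, Mediator subunits (Med) in 28 of 30, translation initiation factors (Eif) in 50 of 55 and centrosomal proteins (Cep) in 33 of 38. Olfactory receptor genes (Olfr) had 0 of 1110, keratin-associated proteins (Krtap) 0 of 56 and vomeronasal receptors (Vmn) 1 of 355. Near-identical copies in the receptor families share reads, and how the authors treated such reads is not given in the sources used here. Solute carriers (Slc), with 193 of 375, lay at percentile 34.4.

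Outside protein-coding genes, 71 of 408 tRNA genes (17.4%, exact 95% interval 13.8 to 21.4%) and 2319 of 12697 lncRNA genes (18.3%) had a peak within 1000 bp of an end, against 186 of 9852 pseudogenes (1.89%). More than 5000 bp from any protein-coding gene end, 40 of 300 tRNA genes (13.3%) still had one. So did 949 of 8852 lncRNA genes (10.7%) and 122 of 8443 pseudogenes (1.44%). Each gene within reach of a peak was counted, so neighbouring genes can share one, which the interval does not allow for. The most peaks inside a gene were found in Arhgap26 (32 in 775 kb), Auts2 (23) and Syn3 (23). Glis3, of the same gene family as Glis2 and picked after its values were seen, had 14 peaks inside its 421415 bp with 61 to 374 IP fragments, and none at an end. The 311 genes within 25% of its length had a median of 3 peaks inside, which places Glis3 at percentile 95.8. The 3 peaks in Cdkn1a placed it at percentile 99.9 of 2453 genes of like length, but they form 1 close cluster. By the same measure, which also counts peaks near an end if centred inside the gene, Glis2, with 2 peaks inside, lay at percentile 88.6, Ptch1, with 1, at 52.2 and Gli1, with 0, at 30.6. One of the 2 in Glis2 is the peak at its higher end, where Pam16 ends as well, so its percentile rests in part on a peak of uncertain gene.

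The tests on gene ends, on an unequal mix of X copies and on broadly active genes were chosen after the result was seen; the other tests below were set before. Gene-end peaks held 1.89 times the IP fragments of other peaks on average. If fragments were simply recovered more readily there, the input would rise alike, but the pooled ratio of IP to input was 1.37 times that elsewhere (bootstrap 95% interval over peaks 1.35 to 1.40), which argues against this as the whole cause. At equal input count, gene-end peaks had the higher median IP in 13 of 14 classes, from 1.18-fold to 2.31-fold. The excess shrank as the input count rose, from 2.31-fold at 1 input fragment to 2.07-fold at 6 and 1.54-fold at 10. It was 1.18-fold at 13 and gone at 14 (0.98-fold), the highest count compared. The comparison thus speaks for peaks of low input more than for those of high input. Recovery of open chromatin by any antibody stays open and cannot be told apart from binding of GLIS2, because no IP from untagged cells was analysed here; the input alone was also higher at gene ends, 1.37-fold in mean count.

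Ribosomal, ciliary and nephronophthisis lists had more end peaks than random lists. For the ciliary and nephronophthisis lists, matching on classes of gene length and density did not remove the excess at 1000 bp. The lower of their 2 percentiles was 99.51 among such random lists. Within 500 bp of an end, the nephronophthisis list lay within the range (percentile 95.2). Of genes over 10000 bp, 54.4% had an end peak, against 46.4% of all genes. Short genes thus had fewer end peaks, and the test could hardly have failed on length. CpG content could not be matched. The lists may instead follow an occupancy of broadly active genes in general. The ribosomal protein list lay at percentile 100, and leukocyte genes and genes of neurons, liver and muscle at 0.015 and 0.04, but these are the values that prompted the hypothesis and they do not test it. It stays open, as does a preference for cilia genes among active genes, since no expression data were used here.

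Peaks on chromosome X had fewer fragments than those on autosomes, with a mean input of 3.79 against 5.63 (5.29 to 5.78 over the 19 autosomes) and a mean IP of 124 against 171. Peaks on X were not more distal, since 42.9% lay at gene ends, against 23.6% to 35.0% on the autosomes. Weaker peaks on X do not explain the input either. It was 0.73 times that of autosomal peaks of equal IP count and location (bootstrap 95% interval 0.70 to 0.75). If IP and input both followed the number of copies alone, a single X in every cell would give 0.5 against autosomal peaks of 2 times the IP count. There 0.60 (0.58 to 0.62) was found. An equal mix of cells with 1 and with 2 X would give 0.75 at 4/3 times the IP count, where 0.67 (0.64 to 0.69) was found. Whether IP per copy was the same on X as on autosomes was not tested, so these values exclude neither case. An unequal mix is possible too, with the matched ratio meeting the assumed dose at 0.64 X copies per autosome copy. However, any ratio in that range would give such a point, and differences in mapping on X were not tested. Some fragments were placed on the Y chromosome: a peak at an end of Eif2s3y had 196 IP and 3 input fragments. Another, 9336 bp from an end of Uba1y, had 47 and 2. Whether reads from elsewhere were placed there was not tested, and the labels do not give the sex of the mice.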
